A study of Mus musculus with 8 samples.

How the data were processed

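The series holds 8 RNA sequencing libraries of macrophages from 7-week-old male C57BL6 mice, made from total RNA with an Illumina TruSeq kit per the labels, 2 in each of 4 groups: saline for 4 h, LPS for 4 h, IFNb for 4 h, and IFNb for 4 h followed by LPS for 4 h. Groups and replicate numbers were taken from the sample labels. Each library came as 1 deposited file of TPM values for 88198 Ensembl mouse transcripts. TPM divides estimated reads by transcript length and scales each library to the same sum. The submitters' processing notes name kallisto, which assigns reads to transcripts by pseudoalignment, and the mm10 build. The kallisto version and options, the transcript set and any filter are not given in the sources used here. No library was pooled and none was left out.

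TPM keeps no record of read number. The sequencing depth of each library is therefore unknown, counting error cannot be given, and low values are less precise than high ones by an unknown amount. A TPM also depends on every other gene of its library: when some genes take more of the sum, the rest fall. A value of 0 can be a failed assignment of shared reads, so a gene at 0 is described as listed at 0. Near-identical paralogs and pseudogenes share reads that pseudoalignment divides between them, and whether strand was used is not given.

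Transcript IDs were matched to GENCODE M21 on GRCm38 (mm10), which held 86119 of the 88198; the other 2079 took 1.01% to 1.95% of the TPM of a library and were left out. TPM was summed over the transcripts of each gene, giving 30284 genes, with the gene ID kept apart for 29 symbols shared by several genes. Genes with at least 1 TPM in at least 2 libraries were tested, 13009 in all. Coordinates count from 1.

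The fixed design assumed read counts and named limma on log TPM for files that hold TPM. The files held TPM, so no count test was run. Values were log2(TPM + 1), and fold changes are on that scale, which understates the change of low genes. A linear model with 1 mean per group was fitted to all 8 libraries in limma 3.58.1 under R 4.3.3, with an intensity trend in the prior variance (limma-trend), and gave 5 differences between groups and the interaction (LPS+IFNb minus LPS, minus IFNb, plus saline). The groups share an estimate of spread from 4 residual degrees of freedom and 2.54 prior degrees of freedom. P-values are two-sided with Benjamini-Hochberg adjustment over the genes of each comparison, and a gene counts as changed at an adjusted p under 0.05, with no minimum fold. Groups of 2 are too small for an outlier test or for counting other splits of the samples.

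There were 40 fixed gene lists. They covered innate signalling, inflammatory mediators, interferon response, antigen presentation, metabolism, stress, housekeeping and markers of peritoneal macrophages and other peritoneal cells. Of these 39 had at least 5 measured members and were tested with camera in limma, which compares a list with all other genes, at its preset correlation between genes of 0.01. Adjustment was over the 39 lists of a comparison. Of 114 passing results, 11 also passed with the correlation estimated from the data: 3 in LPS against saline, 2 in IFNb against saline, 1 in LPS+IFNb against IFNb, 3 in LPS+IFNb against saline and 2 in the interaction. The number of members that changed is given as called over all genes and as adjusted over the list alone.

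Genes were named by a fixed rule with 3 parts. The first took the 8 largest rises and 8 largest falls of a comparison among changed genes with a mean log2(TPM + 1) of at least 3 (a level written for CPM and carried over to TPM), with no overlap between the libraries of the 2 groups (not asked of the interaction), and a symbol that is not that of a predicted gene, pseudogene or antigen receptor segment. The second took members of a list in order of adjusted p, up to 4 per direction. The third took a set of focal genes whatever their p, of which these 13 are given: Tnf, Il6, Il1b, Il12b, Il10, Ifnb1, Cxcl10, Nos2, Isg15, Irf7, Tlr4, Ifnar1 and Socs1. Some items that the rule names are not reported here.

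Alternatives were median-ratio scaling and upper-quartile scaling of the TPM, a pseudocount of 0.1, no filter on low values, a minimum of 5 TPM, a fit to only the 2 groups compared, an adjusted p under 0.01, a minimum change of 2-fold (log2 of 1), the replicate number as a block, each library left out in turn, and for lists also the fry test, which asks whether the genes of a list move one way without reference to other genes. Protein-coding genes outside the mitochondrial genome, rescaled to the same sum, were added after seeing the data. Correlations between comparisons that share the saline libraries were set beside 100 draws of simulated unchanged groups.

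The model was tested on simulated data made from the means and spread of the 13009 genes, with 100 genes changed by a log2 of 1 and 100 by a log2 of 2. Of the former, the test recovered 52 in LPS against saline, 53 in IFNb against saline, 60 in LPS+IFNb against LPS, 60 in LPS+IFNb against IFNb, 55 in LPS+IFNb against saline and 34 in the interaction. Of the latter it recovered 96, 87, 90, 93, 91 and 81 in the same order, with 7, 6, 11, 11, 3 and 9 false calls. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 handled tables and plots.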

Results

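Macrophages came from 7-week-old male C57BL6 mice. Per the labels, mice were stimulated in the peritoneal cavity. RNA sequencing of total RNA gave 8 libraries, 2 in each of 4 groups: saline for 4 h, lipopolysaccharide (LPS, the bacterial outer-membrane component sensed by TLR4) for 4 h, interferon beta (IFNb, a type I interferon) for 4 h, and IFNb for 4 h followed by LPS for 4 h. The 4 groups form a 2 by 2 layout, except for timing: the LPS+IFNb libraries were taken 8 h after IFNb, and none of the 4 groups received IFNb and then saline. Values were deposited as TPM, a length-corrected abundance with the same total in each library, for 88198 transcripts, so depth is unknown. After summing over transcripts, 30284 genes had a value and 13009 were tested. The labels do not say whether the 2 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Levels are mean TPM ± SD with n = 2 libraries per group, and changes are log2 differences of TPM + 1 ± SE from limma, with p adjusted over the 13009 genes. The gene lists and naming rule were fixed before the data were examined. Lists share members, so their results are not independent: other lists hold the antiviral genes Ddx58, Ifih1, Dhx58, Bst2, Stat2, Irf7, Zbp1 and Usp18. A list that passed the camera test at its preset correlation is given with its adjusted p with an estimated correlation, and a list that did not pass with its camera adjusted p.

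The first principal component held 55.2% of the variance and ran from the saline libraries (-88.2 and -94.0) to the LPS+IFNb libraries (66.2 and 64.2), with the other 4 libraries between 3.59 and 22.4. The second held 27.3% and parted LPS (51.0 and 53.1) from IFNb (-59.2 and -61.9). Libraries of 1 group correlated at 0.971 to 0.983 across genes and libraries of different groups at 0.823 to 0.951. Mitochondrially encoded transcripts made up 3.93% and 3.57% of TPM in saline, 3.39% and 3.11% with LPS, 2.62% and 2.84% with IFNb and 2.56% and 2.52% with LPS+IFNb. Saline replicate 2 had 53928 transcripts above 0, against 46998 to 50489 in the other 7 libraries. Genes higher than saline made up more of the TPM after treatment, rising from 11.7% of TPM to 32.1% with LPS, from 11.7% to 34.1% with IFNb and from 11.7% to 41.6% with LPS+IFNb. Scaling by the median ratio of all genes instead moved the median log2 change of all genes by 0.43 in LPS against saline, 0.36 in IFNb against saline, 0.25 in LPS+IFNb against LPS, 0.31 in LPS+IFNb against IFNb, 0.66 in LPS+IFNb against saline and -0.12 in the interaction. Counts called "rescaled" use that scaling.

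LPS against saline gives the response to LPS alone. Secreted inflammatory mediators made up 7 of the 8 largest rises. Tnf, an early inflammatory cytokine, was at 6.87 ± 0.259 TPM in saline and 2082 ± 222 TPM with LPS, a change of 8.04 ± 0.10 (adjusted p = 2.04e-07). Il1b, the precursor of IL-1 beta, went from 6.17 ± 1.26 to 5935 ± 434 TPM, a change of 9.70 ± 0.26 (adjusted p = 1.61e-06), and Cxcl10, a chemokine for activated T cells, from 2.13 ± 0.256 to 3053 ± 215 TPM, a change of 9.93 ± 0.12 (adjusted p = 2.04e-07). The neutrophil chemokines Cxcl1, Cxcl2 and Cxcl3 rose by 8.50 ± 0.19, 8.23 ± 0.21 and 7.79 ± 0.26, the macrophage chemokine Ccl4 by 8.01 ± 0.15 and the exception among the 8, the interferon-induced antiviral gene Ifit1, by 7.96 ± 0.15. Among the largest falls were those of Fbxo32, a ubiquitin ligase subunit (-4.95 ± 0.13), the chemokine receptor Cxcr4 (-4.91 ± 0.16), the GTPase Rhov (-4.19 ± 0.12), the ARF-like GTPase Arl11 (-4.18 ± 0.11), the myeloid receptor Cd300lb (-4.08 ± 0.13) and the glucocorticoid-induced Tsc22d3 (-4.04 ± 0.09). Ifnb1 was listed at 0 in both saline libraries and at 10.88 and 10.01 TPM in the LPS libraries.

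Proinflammatory cytokines rose as a group. All 23 measured proinflammatory cytokines rose (23 adjusted over the list alone), among them, beside Tnf and Il1b, Il1a (7.41 ± 0.15), the TNF-family ligand Tnfsf9 (7.57 ± 0.20) and Il27 (6.98 ± 0.18), and the list's median was 4.46 (camera adjusted p = 1.98e-24, or adjusted p = 0.0125 with an estimated correlation). Of 23 chemokines 19 rose and 1 fell (19 and 1 adjusted over the list alone), with Ccl5 at 5.91 ± 0.07 and Ccl3 at 6.67 ± 0.12. This list had adjusted p = 0.0676 with an estimated correlation. Of 28 NF-kB pathway genes 26 rose and 1 fell (26 and 1 adjusted over the list alone; adjusted p = 0.0676 with an estimated correlation), among them the mitochondrial superoxide dismutase Sod2 (3.45 ± 0.08) and the NF-kB inhibitors Nfkbia (4.94 ± 0.12) and Tnfaip3 (4.89 ± 0.13). Feedback regulators rose in 22 of 26 cases and fell in 1 (22 and 1 adjusted over the list alone; adjusted p = 0.0637 with an estimated correlation), with the interferon-pathway protease Usp18 at 4.29 ± 0.10. The TLR4 sensing and signalling list was split, 10 higher and 7 lower of 22 (10 and 7 adjusted over the list alone; adjusted p = 0.370 with an estimated correlation). The LPS co-receptor Cd14 rose by 4.58 ± 0.25 and the adaptor Myd88 by 1.85 ± 0.07. Tlr4 itself fell from 42.0 ± 2.96 to 11.4 ± 1.08 TPM (-1.80 ± 0.13).

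LPS alone also raised interferon-response genes. Of 57 antiviral interferon-stimulated genes 55 rose and none fell (55 and 0 adjusted over the list alone; adjusted p = 0.0446 with an estimated correlation), with a median of 3.0. The antiviral enzyme Rsad2 rose by 6.40 ± 0.10, the nucleotide kinase Cmpk2 by 6.26 ± 0.09 and the GTPase Mx1 by 6.68 ± 0.11. Of 18 guanylate-binding proteins and immunity-related GTPases, which act against intracellular microbes, 14 rose (14 adjusted over the list alone; adjusted p = 0.0446 with an estimated correlation), with Gbp5 at 7.33 ± 0.08. The costimulation and adhesion list had 14 of 16 higher (14 adjusted over the list alone; adjusted p = 0.0743 with an estimated correlation), with the adhesion molecule Icam1 at 5.36 ± 0.14 and Cd40 at 5.43 ± 0.16. MHC class I presentation had 15 higher and 2 lower of 23 (15 and 2 adjusted over the list alone; adjusted p = 0.225 with an estimated correlation), with the peptide transporter Tap1 at 2.57 ± 0.07. None of 11 class II genes passed (list camera adjusted p = 0.726). Acod1, which makes itaconate, rose by 7.37 ± 0.11 and the prostaglandin synthase Ptgs2 by 7.28 ± 0.22, in a list of antimicrobial and arachidonate effectors with 9 higher and 5 lower of 22 (9 and 5 adjusted over the list alone; adjusted p = 0.225 with an estimated correlation). Among cell type markers, 4 of 16 monocyte and small peritoneal macrophage genes rose and 3 fell (rescaled 6 and 2), with Vcan at 4.27 ± 0.27 and Ccr2 at -2.55 ± 0.19. Of 21 B cell genes 1 rose and 8 fell, with Cd79b at -1.84 ± 0.15. Neither list passed (camera adjusted p = 0.151 and 0.336).

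Further lists passed upward (adjusted p with an estimated correlation, counts adjusted over the list alone the same unless given). The interferon receptor, JAK-STAT and IRF list had 13 higher and 1 lower of 21 (adjusted p = 0.115), with Stat2 at 3.39 ± 0.08. Nucleic acid and other pattern receptors had 13 higher and 5 lower of 23 (adjusted p = 0.0676). Inflammasome and cell death had 12 higher and 8 lower of 23 (adjusted p = 0.313). Handling and stress genes had 11 higher and 4 lower of 20 (adjusted p = 0.225), with Junb at 2.83 ± 0.14 and Ier2 at 2.16 ± 0.12. Glycolysis had 6 higher and 3 lower of 23 (5 and 2 adjusted over the list alone, adjusted p = 0.646) and a median of -0.16, rescaled 0.30. This list did not pass with fry or without Saline replicate 1 or LPS replicate 2. Hypoxia and angiogenic factors had 5 higher and 2 lower of 15 (4 and 1 adjusted over the list alone, adjusted p = 0.645), not passing after rescaling or without LPS replicate 2. Dendritic cell markers had 3 higher and 0 lower of 15 (adjusted p = 0.162), not passing after rescaling or at a minimum of 5 TPM.

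In total 7032 of 13009 genes differed between LPS and saline, 1664 higher and 5368 lower. The excess of falls depended on the scale. Rescaled values gave 2718 higher and 2254 lower, and upper-quartile scaling 1991 higher and 3879 lower.

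IFNb against saline gives the response to IFNb alone. Interferon-induced genes made up all of the 8 largest rises. Isg15, a ubiquitin-like antiviral modifier, went from 10.8 ± 3.63 to 2075 ± 99.1 TPM, a change of 7.50 ± 0.20 (adjusted p = 1.11e-06), and Irf7, the transcription factor that amplifies interferon production, from 55.4 ± 22.9 to 2887 ± 255 TPM (5.74 ± 0.25, adjusted p = 1.06e-05). The largest rises included those of Ifit2 (9.11 ± 0.28), Cxcl10 (9.11 ± 0.12), Ifit1bl1 (9.09 ± 0.17) and Cmpk2 (8.93 ± 0.09). Ifit3 and Ifit3b, near-identical paralogs whose reads cannot be parted with certainty, were estimated at 8.79 ± 0.23 and 8.44 ± 0.18. All 57 antiviral interferon-stimulated genes rose (57 adjusted over the list alone) with a median of 4.58 (adjusted p = 0.0377 with an estimated correlation), as did all 18 guanylate-binding proteins and immunity-related GTPases (18 adjusted over the list alone; adjusted p = 0.0377 with an estimated correlation), among them Gbp2 (6.58 ± 0.07) and Iigp1 (8.15 ± 0.12). Of 23 MHC class I genes 18 rose (20 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation), with Tap1 at 3.77 ± 0.07 and the immunoproteasome subunit Psmb10 at 3.34 ± 0.08. In the interferon receptor, JAK-STAT and IRF list 10 rose and 4 fell of 21 (10 and 4 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation). Ifngr1, a chain of the interferon gamma receptor, fell (-2.28 ± 0.15) and Ifnar1, a chain of the type I interferon receptor, had -0.15 ± 0.09 (adjusted p = 0.232), a sign that turned when rescaled (0.24). Socs1, a feedback inhibitor of JAK signalling, rose by 6.30 ± 0.17.

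IFNb alone raised some inflammatory mediators and not others. Of 23 proinflammatory cytokines 9 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.0701 with an estimated correlation). Tnf reached 28.9 ± 2.35 TPM (1.92 ± 0.10), Il6 7.28 ± 2.35 TPM from 0.402 ± 0.330 (2.55 ± 0.25), the death ligand Tnfsf10 rose by 6.65 ± 0.15 and Il15, a growth factor for NK cells, by 2.98 ± 0.09. Il1a fell (-1.51 ± 0.15), while Il1b had -0.50 ± 0.26 (adjusted p = 0.152, or -0.92 with adjusted p = 0.0130 without IFNb replicate 2) and Il12b -0.49 ± 0.64 (adjusted p = 0.554). The anti-inflammatory cytokine Il10 rose from 0.238 ± 0.121 to 16.3 ± 0.846 TPM (3.81 ± 0.13) and the nitric oxide synthase Nos2 from 0.0952 ± 0.0298 to 9.48 ± 2.20 TPM (3.24 ± 0.32). With a pseudocount of 0.1 the changes of the low-level genes Il6 and Nos2 came to 4.02 and 5.61. Ifnb1 was listed at 0 in both saline libraries and at 0.229 and 0.101 TPM after IFNb. Of 23 chemokines 12 rose and 4 fell (12 and 5 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), with the monocyte chemokines Ccl12 at 7.33 ± 0.16 and Ccl2 at 6.06 ± 0.21. In the inflammasome and cell death list 13 rose and 2 fell of 23 (13 and 2 adjusted over the list alone; adjusted p = 0.206 with an estimated correlation), with the nucleic acid sensor Zbp1 at 5.74 ± 0.10 and the inflammatory caspase Casp4 at 3.43 ± 0.08.

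Several metabolic lists were lower with IFNb as deposited, while glycolysis passed upward. Of 20 TCA cycle genes 14 fell (rescaled 5), with the isocitrate dehydrogenases Idh1 at -3.03 ± 0.13 and Idh2 at -1.19 ± 0.11. The list had adjusted p = 0.206 with an estimated correlation and did not pass after rescaling. Cholesterol synthesis and uptake fell in 16 of 22 genes (rescaled 8; adjusted p = 0.206 with an estimated correlation), with Msmo1 at -0.99 ± 0.09 (rescaled -0.60) and the squalene synthase Fdft1 at -1.35 ± 0.16, and the NRF2 antioxidant list in 10 of 14 (rescaled 5; adjusted p = 0.206 with an estimated correlation), with the thioredoxin reductase Txnrd1 at -1.79 ± 0.12. Both lists stopped passing when Saline replicate 1 was left out or at least 5 TPM was asked for. Ribosomal protein genes fell in 31 of 47 cases as deposited and 3 rescaled (adjusted p = 0.669 with an estimated correlation, not passing after rescaling), and mitochondrially encoded genes in 10 of 13 as deposited and 0 rescaled (adjusted p = 0.684 with an estimated correlation, not passing after rescaling, with upper-quartile scaling, or without Saline replicate 1 or IFNb replicate 1). Glycolysis had 6 higher and 3 lower of 23 (6 and 3 adjusted over the list alone, adjusted p = 0.705 with an estimated correlation). It did not pass with fry or without IFNb replicate 1. Beside these, the monocyte and small peritoneal macrophage markers had 5 of 16 higher and 1 lower (adjusted p = 0.206 with an estimated correlation). Plac8 rose by 3.87 ± 0.20 and Vcan by 5.14 ± 0.27, while Cx3cr1 fell (-2.10 ± 0.19, or -3.20 with a pseudocount of 0.1). Of 20 T and NK cell genes 3 rose and 4 fell (camera adjusted p = 0.332), with the activating receptor Klrk1 going from 2.58 ± 1.08 to 88.9 ± 13.5 TPM (4.68 ± 0.25) and the T cell costimulatory receptor Cd28 at -1.99 ± 0.16. Gzmb, a granzyme, was listed at 0 in saline and at 4.64 and 6.28 TPM with IFNb.

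Further lists passed upward (adjusted p with an estimated correlation, counts adjusted over the list alone the same unless given). Feedback regulators had 13 higher and 8 lower of 26 (14 and 8 adjusted over the list alone, adjusted p = 0.206). The NF-kB pathway had 10 higher and 6 lower of 28 (11 and 6 adjusted over the list alone, adjusted p = 0.605), not passing with fry or without Saline replicate 1. Nucleic acid and other pattern receptors had 13 higher and 6 lower of 23 (adjusted p = 0.142). Costimulation and adhesion had 11 higher and 3 lower of 16 (adjusted p = 0.206). Complement had 7 higher and 5 lower of 18 (adjusted p = 0.206), not passing with fry and the replicate block. Alternative activation had 5 higher and 3 lower of 16 (adjusted p = 0.206), not passing after rescaling. Dendritic cell markers had 5 higher and 2 lower of 15 (adjusted p = 0.206). Its call was lost with either other scaling, at a minimum of 5 TPM or without Saline replicate 1.

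In total 6717 genes differed between IFNb and saline, 1697 higher and 5020 lower. Rescaled there were 4367, 2429 higher and 1938 lower, and without IFNb replicate 1 there were 1378 higher and 3339 lower. The effects of LPS and of IFNb, both against the same saline libraries, correlated at r = 0.550 (Spearman 0.502) across 13009 genes, which are not independent replicates. Simulated unchanged groups gave r = 0.502 on average and 0.547 at most over 100 draws. The covariance was 0.608 observed and 0.0404 simulated, a difference of 0.568. Genes higher with both numbered 747 against 217 for independent lists, and genes lower with both 3357 against 2071. Part of either excess may come from the shared saline libraries, which are too few to split. Genes moving in opposite directions numbered 608.

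**Figure D1:**
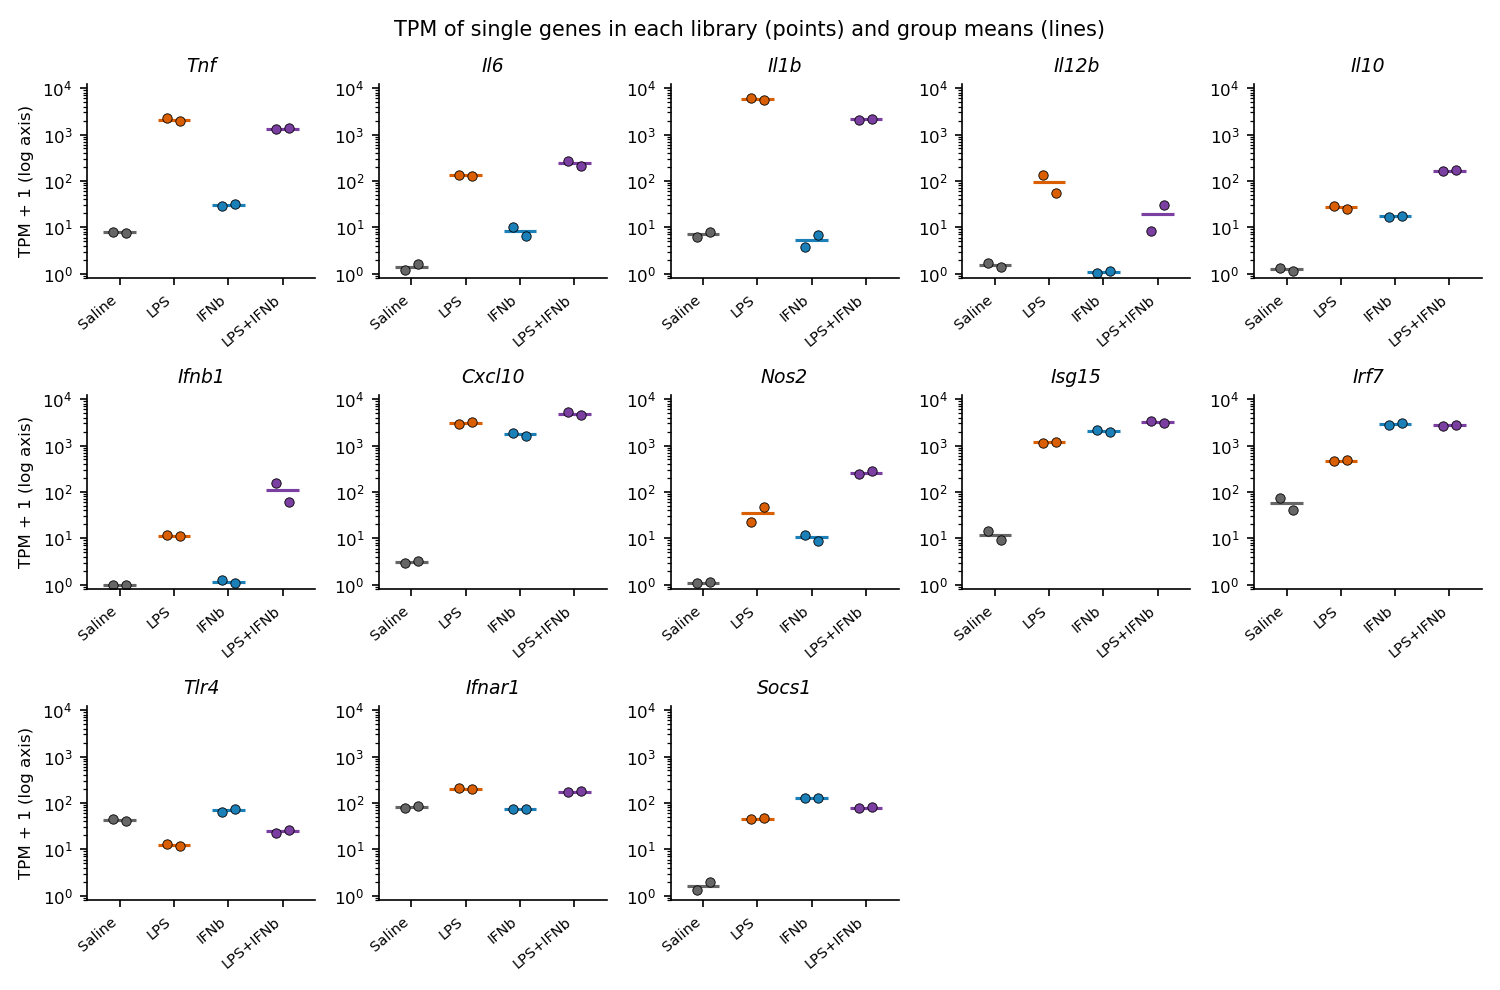
TPM of 13 genes in each of the 8 libraries on a log axis of TPM + 1, with 1 point per library and a bar at the mean of each group of 2. Il6, Il10, Ifnb1 and Nos2 lie higher with LPS+IFNb than with LPS, and Tnf, Il1b and Il12b lower.

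LPS+IFNb against LPS sets IFNb followed by LPS beside LPS alone, for the question in the series title, what prior IFNb does to the response to LPS. The difference also holds IFNb's own effect and the longer time since IFNb. Whether the change with LPS itself differed after IFNb is asked by the interaction below. Cytokine transcripts moved both ways. Il6 (chromosome 5, 30013114 to 30019981) was at 130.3 ± 1.63 TPM with LPS and 237 ± 45.9 TPM with LPS+IFNb, a change of 0.84 ± 0.25 (adjusted p = 0.0413). Nos2 (chromosome 11, 78920787 to 78960254) went from 33.6 ± 16.5 to 259 ± 21.6 TPM (3.0 ± 0.32, adjusted p = 0.00112) and Il10 (chromosome 1, 131019845 to 131024974) from 25.8 ± 3.56 to 164 ± 5.96 TPM (2.63 ± 0.13, adjusted p = 9.94e-05). Ifnb1 (chromosome 4, 88522025 to 88522774) went from 10.4 ± 0.613 to 109 ± 69.3 TPM, with 158 and 59.5 TPM in the 2 LPS+IFNb libraries (3.10 ± 0.40, adjusted p = 0.00224). Tnf (chromosome 17, 35199381 to 35202007) was lower, 2082 ± 222 against 1327 ± 60.5 TPM (-0.65 ± 0.10, adjusted p = 0.00486), as was Il1b (chromosome 2, 129364570 to 129371139) at 5935 ± 434 against 2122 ± 41.8 TPM (-1.48 ± 0.26, adjusted p = 0.00678). Il12b, a subunit shared by IL-12 and IL-23, had 130 and 54.2 TPM with LPS and 7.43 and 29.8 TPM with LPS+IFNb (-2.40 ± 0.64, adjusted p = 0.0284). The calls of Il6 and Il12b were not firm. That of Il6 was lost with a pseudocount of 0.1 (adjusted p = 0.205), with no filter on low values (0.10), and without LPS replicate 1 (0.131), LPS replicate 2 (0.139), LPS+IFNb replicate 1 (0.194) or LPS+IFNb replicate 2 (0.0635). That of Il12b was lost with no filter on low values (adjusted p = 0.0818), with only the 2 groups in the fit (0.0835), and without LPS replicate 1 (0.139), IFNb replicate 1 (0.0506), IFNb replicate 2 (0.0507) or LPS+IFNb replicate 1 (0.0964, with a change of -1.47). That of Tnf was lost after rescaling (-0.37, adjusted p = 0.0664). Coordinates are from GENCODE M21 on mm10.

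Of 23 proinflammatory cytokines 8 were higher and 8 lower with LPS+IFNb than with LPS (8 and 8 adjusted over the list alone), and rescaled 9 and 4. The list as a whole did not pass (camera adjusted p = 0.110). Higher were Tnfsf10 (3.29 ± 0.15), Il15 (1.38 ± 0.09) and Il18 (1.63 ± 0.19). Lower were Il23a, the other IL-23 subunit (-3.08 ± 0.23), and Il1a (-1.12 ± 0.15). The chemokine list had 6 higher and 10 lower of 23 (7 and 11 adjusted over the list alone; rescaled 8 and 6; camera adjusted p = 0.843). Ccl12 rose by 4.28 ± 0.16, Ccl8 by 5.06 ± 0.77, Cxcl11 by 1.5 ± 0.24 and Cxcl10 by 0.67 ± 0.12, while Ccl9 (-1.57 ± 0.10), Cxcl3 (-4.01 ± 0.26), Cxcl1 (-1.52 ± 0.19) and Ccl22 (-1.99 ± 0.26) fell. None of 28 NF-kB pathway genes was higher and 10 were lower (0 and 10 adjusted over the list alone), with Icam1 at -1.19 ± 0.14. Rescaled, 3 were higher and 3 lower, and the list did not pass (camera adjusted p = 0.428). TLR4 sensing and signalling had 3 higher and 10 lower of 22 (camera adjusted p = 0.509). Myd88 (0.66 ± 0.07) and Tlr4 (0.99 ± 0.13) rose, and the kinases Mapk14 (-2.56 ± 0.13) and Mapkapk2 (-0.75 ± 0.09, rescaled -0.47) fell. Feedback regulators rose in 11 and fell in 7 of 26 cases (11 and 7 adjusted over the list alone; adjusted p = 0.406 with an estimated correlation). Il10, Usp18 (1.68 ± 0.10) and Cd274, which encodes PD-L1 (1.0 ± 0.07), were higher and Irak3 (-1.64 ± 0.13) lower.

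Interferon-response genes were higher with LPS+IFNb than with LPS. Passing lists have adjusted p with an estimated correlation, and counts adjusted over the list alone were the same unless given. Of 57 antiviral interferon-stimulated genes 49 were higher and none lower (51 and 0 adjusted over the list alone), with a median of 1.15, and adjusted p = 0.0991. Epsti1 rose by 2.84 ± 0.08, the exonuclease Isg20 by 3.29 ± 0.11 and Isg15 by 1.45 ± 0.20. All 18 guanylate-binding proteins and immunity-related GTPases were higher (adjusted p = 0.0991), with Gbp2 at 2.94 ± 0.07 and Iigp1 at 4.12 ± 0.12, though members of this family share sequence. MHC class I presentation rose in 18 of 23 cases (19 adjusted over the list alone; adjusted p = 0.183), with Psmb10 at 2.05 ± 0.08 and H2-T23 at 1.40 ± 0.08. None of 11 class II genes passed (camera adjusted p = 0.509). Interferon receptor, JAK-STAT and IRF genes rose in 7 and fell in 4 of 21 cases (adjusted p = 0.406), with Irf7 at 2.51 ± 0.25 and Ifngr1 at -1.44 ± 0.15. Nucleic acid and other pattern receptors rose in 8 and fell in 5 of 23 cases (adjusted p = 0.297), with the double-stranded RNA receptor Tlr3 at 3.18 ± 0.11. In the inflammasome and cell death list 15 rose and 2 fell of 23 (adjusted p = 0.183), with the necroptosis effector Mlkl at 2.47 ± 0.11. Costimulation and adhesion had 9 higher and 4 lower of 16 (adjusted p = 0.406), with Cd86 at 2.51 ± 0.15 and the hyaluronan receptor Cd44 at -1.38 ± 0.10.

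The largest rises over LPS were of the interferon-induced Ifit1bl1 (5.15 ± 0.17), Ccl8, the fibrinogen-like immune regulator Fgl2 (4.48 ± 0.14), Ccl12, Iigp1, the endothelial lipase Lipg (4.09 ± 0.28), Ifi44 (3.76 ± 0.23) and the IL-18 inhibitor Il18bp (3.67 ± 0.17). The largest falls were of Cxcl3, the caveolar protein Cav1 (-2.66 ± 0.20), Mapk14, the cystine transporter subunit Slc7a11 (-2.55 ± 0.21), the proton channel Hvcn1 (-2.54 ± 0.12), Mmd (-2.45 ± 0.12), the oxidised LDL receptor Olr1 (-2.42 ± 0.23) and the myeloid receptor Clec5a (-2.40 ± 0.23).

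Several metabolic and translation lists were lower with LPS+IFNb than LPS as deposited, less so rescaled (adjusted p with an estimated correlation). TCA cycle genes fell in 16 of 20 cases (17 adjusted over the list alone; rescaled 5; adjusted p = 0.183), with Idh1 at -1.99 ± 0.13 and the citrate synthase Cs at -0.86 ± 0.08. NRF2 antioxidant genes had 1 higher and 10 lower of 14 (1 and 10 adjusted over the list alone; rescaled 1 and 5; adjusted p = 0.224), with Slc7a11 and Txnrd1 (-1.41 ± 0.12) lower. Cholesterol synthesis and uptake fell in 9 of 22 cases (10 adjusted over the list alone; rescaled 6; adjusted p = 0.297, not passing at a minimum of 5 TPM), with Msmo1 at -0.88 ± 0.09. Ribosomal protein genes fell in 33 of 47 cases (36 adjusted over the list alone) and rescaled in 4 (adjusted p = 0.488), mitochondrially encoded genes in 9 of 13 (10 adjusted over the list alone) and rescaled in 0 (adjusted p = 0.559, not passing after rescaling), and oxidative phosphorylation in 11 of 32 with 1 higher (15 and 1 adjusted over the list alone), rescaled 0 and 2 (adjusted p = 0.559). The oxidative phosphorylation list did not pass with either other scaling, at a minimum of 5 TPM or with any of the LPS and LPS+IFNb libraries left out. Lysosome and phagocytosis had 6 higher and 2 lower of 23 (6 and 2 adjusted over the list alone; adjusted p = 0.425), with the Fc receptors Fcgr1 at 3.29 ± 0.09 and Fcgr4 at 2.38 ± 0.08. Camera's direction was up, the list's median was -0.03 (rescaled 0.24) and its mean 0.34. Alternative activation had 6 higher and 3 lower of 16 (6 and 3 adjusted over the list alone; adjusted p = 0.183), with Pdcd1lg2, which encodes PD-L2, at 1.89 ± 0.17, the mannose receptor Mrc1 at 0.95 ± 0.11 and Ccl22 at -1.99 ± 0.26. Handling and stress genes had 6 higher and 1 lower of 20 (6 and 1 adjusted over the list alone; adjusted p = 0.297, not passing with fry).

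Cell type markers moved beside these groups. Of 16 monocyte and small peritoneal macrophage genes 7 were higher and 1 lower (7 and 1 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation), with Plac8 at 2.87 ± 0.20 and Cx3cr1 at -1.13 ± 0.19 (-2.24 with a pseudocount of 0.1). The T and NK cell list had 4 higher and 1 lower of 20 (4 and 1 adjusted over the list alone; adjusted p = 0.617 with an estimated correlation; not passing after rescaling, with fry or without LPS+IFNb replicate 2), the higher ones being Klrk1 (3.32 ± 0.25), Gzmb (2.66 ± 0.22), Gzma (1.75 ± 0.19) and Prf1 (1.01 ± 0.26, or 2.16 with a pseudocount of 0.1). The call of Prf1 was lost without LPS replicate 1 (adjusted p = 0.0828), LPS replicate 2 (0.105) or LPS+IFNb replicate 2 (0.123). None of 21 B cell genes passed (camera adjusted p = 0.493), nor of 9 mast cell genes (camera adjusted p = 0.637) or 5 erythroid and platelet genes (camera adjusted p = 0.425). Neutrophil markers had 1 higher and 3 lower of 15 (camera adjusted p = 0.832), eosinophil markers 1 and 0 of 5 (camera adjusted p = 0.40), dendritic cell markers 2 and 2 of 15 (camera adjusted p = 0.0685), mesothelial and stromal markers 2 and 0 of 19 (camera adjusted p = 0.102) and large peritoneal macrophage markers 2 and 5 of 24 (camera adjusted p = 0.816). The dendritic cell list passed upward without IFNb replicate 1 (adjusted p = 0.0447) or IFNb replicate 2 (0.0449), and the mesothelial list without LPS replicate 2 (0.00631) or LPS+IFNb replicate 2 (0.00789). Of the remaining lists, complement had 4 higher and 3 lower of 18 (adjusted p = 0.297 with an estimated correlation) and hypoxia and angiogenic factors 2 and 0 of 15 (adjusted p = 0.617 with an estimated correlation), both not passing after rescaling, with fry, or without LPS replicate 1 or LPS+IFNb replicate 1. Glycolysis had 3 and 1 of 23 (camera adjusted p = 0.0928), antimicrobial and arachidonate effectors 3 and 5 of 22 (camera adjusted p = 0.832), cholesterol efflux and LXR targets 1 and 6 of 13 (camera adjusted p = 0.870), cell cycle 4 and 2 of 24 (camera adjusted p = 0.509) and the unfolded protein response 2 and 4 of 19 (camera adjusted p = 0.830). Glycolysis passed upward without LPS replicate 2 (adjusted p = 0.00226) or LPS+IFNb replicate 2 (0.0191).

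In total 4529 genes differed between LPS+IFNb and LPS, 1400 higher and 3129 lower. Rescaled there were 1989 higher and 1368 lower, and with upper-quartile scaling 1664 higher and 2076 lower. The count was 2723 without LPS replicate 1, 2740 without LPS replicate 2, 2752 without LPS+IFNb replicate 1 and 2892 without LPS+IFNb replicate 2.

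LPS+IFNb against IFNb gives the response to LPS in cells that had received IFNb. Il1b rose from 4.23 ± 2.08 to 2122 ± 41.8 TPM (8.73 ± 0.26, adjusted p = 7.40e-06), Il1a by 7.80 ± 0.15 and Tnf from 28.9 ± 2.35 to 1327 ± 60.5 TPM (5.48 ± 0.10, adjusted p = 2.53e-06). Hamp, which encodes the iron-regulating hormone hepcidin, went from 0.254 ± 0.0208 to 179.7 ± 10.1 TPM (7.17 ± 0.12), and the largest rises included also Cxcl1 (7.50 ± 0.19), Cxcl2 (7.46 ± 0.21), Tnfsf9 (7.04 ± 0.20), the GTPase Rnd1 (6.81 ± 0.31) and Ptgs2 (6.75 ± 0.22). Falls were led by Fbxo32 (-4.32 ± 0.13), the myeloid transcription factor Cebpa (-3.52 ± 0.17), Rhov (-3.31 ± 0.12) and Arl11 (-3.24 ± 0.11). Of 23 proinflammatory cytokines 20 rose and 1, Tnfsf10 (-1.38 ± 0.15), fell (20 and 1 adjusted over the list alone; adjusted p = 0.0127 with an estimated correlation). Chemokines rose in 15 of 23 cases (15 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation), with Ccl5 at 4.80 ± 0.07, and NF-kB pathway genes rose in 24 and fell in 1 of 28 (24 and 2 adjusted over the list alone; adjusted p = 0.117 with an estimated correlation), with Nfkbia at 4.14 ± 0.12.

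Most antiviral interferon-stimulated genes did not pass between LPS+IFNb and IFNb. Of the 57, 6 were higher and 13 lower as deposited (5 and 11 adjusted over the list alone), but 9 and 1 rescaled. The list's median turned from -0.17 to 0.17 (camera adjusted p = 0.807). Rescaled, the list passed upward (adjusted p = 0.0358). The interferon receptor, JAK-STAT and IRF list passed upward, with 9 higher and 3 lower of 21 (11 and 3 adjusted over the list alone, rescaled 13 and 1, adjusted p = 0.30 with an estimated correlation), and Ifnar1 at 1.23 ± 0.09. Ifi205 was higher (1.11 ± 0.14), and Stat2 (-0.72 ± 0.08, rescaled -0.38) and Cmpk2 (-0.56 ± 0.09) were lower, the latter not after rescaling (-0.21, adjusted p = 0.205) or with upper-quartile scaling (-0.35, adjusted p = 0.0541). Guanylate-binding proteins and immunity-related GTPases had 1 higher and 4 lower of 18 (rescaled 2 and 1; camera adjusted p = 0.807) and MHC class I presentation 3 and 4 of 23 (rescaled 7 and 1; camera adjusted p = 0.323). The MHC class I list passed upward when rescaled (adjusted p = 0.0176) and with upper-quartile scaling (0.0458). Irf7 was at 2887 ± 255 TPM with IFNb and 2708 ± 157 TPM with LPS+IFNb (-0.09 ± 0.25, adjusted p = 0.796, with a positive sign when rescaled, 0.25, or with upper-quartile scaling, 0.12). In the monocyte list 1 rose and 2 fell of 16 (camera adjusted p = 0.739), with Ccr2 at -1.67 ± 0.19, and in the T and NK cell list 1 rose and 2 fell of 20 (camera adjusted p = 0.0775). The latter list passed upward without IFNb replicate 2 (adjusted p = 0.0110) or LPS+IFNb replicate 1 (0.0190). Handling and stress genes rose in 10 and fell in 1 of 20 cases (12 and 1 adjusted over the list alone; adjusted p = 0.127 with an estimated correlation), with the immediate-early genes Ier2 at 3.48 ± 0.12 and Junb at 3.22 ± 0.14.

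Further lists passed upward (adjusted p with an estimated correlation, counts adjusted over the list alone the same unless given). Feedback regulators had 19 higher and 3 lower of 26 (19 and 4 adjusted over the list alone, adjusted p = 0.117). Costimulation and adhesion had 10 higher and 2 lower of 16 (adjusted p = 0.237), and antimicrobial and arachidonate effectors had 9 higher and 3 lower of 22 (9 and 4 adjusted over the list alone, adjusted p = 0.237). TLR4 sensing and signalling had 6 higher and 5 lower of 22 (adjusted p = 0.603), not passing with fry. Nucleic acid and other pattern receptors had 7 higher and 6 lower of 23 (8 and 8 adjusted over the list alone, adjusted p = 0.386) and a median of -0.14, rescaled 0.20. This list did not pass without Saline replicate 1 or Saline replicate 2. Hypoxia and angiogenic factors had 5 higher and 1 lower of 15 (adjusted p = 0.603). Alternative activation had 4 higher and 1 lower of 16 (adjusted p = 0.24) and a median of -0.06, rescaled 0.28, and did not pass without IFNb replicate 2. Glycolysis had 5 higher and 1 lower of 23 (adjusted p = 0.756) and a median of -0.18, rescaled 0.16. Its call was lost with fry or without LPS replicate 1, LPS replicate 2, IFNb replicate 2 or LPS+IFNb replicate 1. The TCA cycle passed downward, with 0 higher and 10 lower of 20 (0 and 12 adjusted over the list alone, adjusted p = 0.472 with an estimated correlation) and rescaled 0 and 0. It did not pass with either other scaling, at a minimum of 5 TPM, or without LPS replicate 1, LPS replicate 2, IFNb replicate 2 or LPS+IFNb replicate 1. Oxidative phosphorylation also passed downward, with 0 higher and 14 lower of 32 (0 and 14 adjusted over the list alone, adjusted p = 0.603 with an estimated correlation) and rescaled 1 and 0. It did not pass with either other scaling, at a minimum of 5 TPM or without IFNb replicate 2.

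Among cell type markers, 3 lists passed upward on few genes. Large peritoneal macrophage markers had 3 higher and 1 lower of 24 (2 and 1 adjusted over the list alone, adjusted p = 0.664 with an estimated correlation). This list did not pass after rescaling, with fry, or without IFNb replicate 2 or LPS+IFNb replicate 1. Neutrophil markers had 2 higher and 0 lower of 15 (2 and 0 adjusted over the list alone, adjusted p = 0.664 with an estimated correlation) and a median of -0.08, rescaled 0.19. This list's call was lost with either other scaling, at a minimum of 5 TPM, with fry, or without LPS replicate 1, LPS replicate 2, IFNb replicate 2 or LPS+IFNb replicate 1. Dendritic cell markers had 2 higher and 0 lower of 15 (2 and 0 adjusted over the list alone, adjusted p = 0.266 with an estimated correlation). The call was lost with either other scaling, at a minimum of 5 TPM, or without Saline replicate 1, Saline replicate 2, IFNb replicate 1 or LPS+IFNb replicate 1.

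In total 5107 genes differed between LPS+IFNb and IFNb, 1140 higher and 3967 lower. Rescaled there were 3211, 1788 higher and 1423 lower, and with upper-quartile scaling 1463 higher and 2128 lower. The count was 2786 without IFNb replicate 1, 2491 without IFNb replicate 2, 2832 without LPS+IFNb replicate 1 and 3363 without LPS+IFNb replicate 2.

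LPS+IFNb against saline gives the response to both treatments. Cxcl10 reached 4865 ± 531 TPM (10.60 ± 0.12, adjusted p = 8.25e-08), Il6 237 ± 45.9 TPM (7.41 ± 0.25), Il10 164 ± 5.96 TPM (7.06 ± 0.13) and Nos2 259 ± 21.6 TPM (7.89 ± 0.32). The monocyte chemokine Ccl7 rose by 9.09 ± 0.39 and the interferon-induced Ifi205 by 8.36 ± 0.14. Arhgap19 (-5.01 ± 0.27) and Cebpa (-4.62 ± 0.17) fell. All 23 proinflammatory cytokines (23 adjusted over the list alone; adjusted p = 0.0153 with an estimated correlation), all 57 antiviral interferon-stimulated genes (57 adjusted over the list alone; adjusted p = 0.0359 with an estimated correlation) and all 18 guanylate-binding proteins and immunity-related GTPases (18 adjusted over the list alone; adjusted p = 0.0359 with an estimated correlation) were higher. Oxidative phosphorylation fell in 28 of 32 genes with a median of -0.58, ribosomal proteins in 37 of 47 with a median of -0.62 and mitochondrially encoded genes in 11 of 13 with a median of -0.68, and rescaled all 3 medians turned positive (0.15, 0.12 and 0.06). With an estimated correlation the lists had adjusted p = 0.501, 0.656 and 0.671, and with upper-quartile scaling none of the 3 passed. TCA cycle genes fell in 19 of 20 cases (rescaled 5; adjusted p = 0.160 with an estimated correlation, not passing after rescaling), with Idh1 at -3.81 ± 0.13. Monocyte markers had 6 higher and 2 lower of 16 (adjusted p = 0.106 with an estimated correlation). Further lists passed upward (adjusted p with an estimated correlation). Chemokines had 18 higher and 1 lower of 23 (adjusted p = 0.0819), feedback regulators 22 and 2 of 26 (adjusted p = 0.0682) and the NF-kB pathway 25 and 2 of 28 (adjusted p = 0.0819). Other pattern receptors had 15 higher and 4 lower of 23 (adjusted p = 0.0682) and interferon receptor, JAK-STAT and IRF genes 15 and 2 of 21 (adjusted p = 0.0860). MHC class I presentation had 20 higher and 2 lower of 23 (adjusted p = 0.0964), costimulation and adhesion 14 and 1 of 16 (adjusted p = 0.0819) and antimicrobial and arachidonate effectors 9 and 6 of 22 (adjusted p = 0.237). Inflammasome and cell death had 14 higher and 7 lower of 23 (adjusted p = 0.106), complement 6 and 5 of 18 (adjusted p = 0.106) and alternative activation 8 and 1 of 16 (adjusted p = 0.0819). Handling and stress had 11 higher and 2 lower of 20 (adjusted p = 0.106) and dendritic cell markers 7 and 2 of 15 (adjusted p = 0.0860). Adjusted over the list alone, these 13 lists had the same counts. Glycolysis had 8 higher and 5 lower of 23 (8 and 5 adjusted over the list alone, adjusted p = 0.619 with an estimated correlation) and a median of -0.06, rescaled 0.67, not passing with fry and the replicate block. Hypoxia and angiogenic factors had 7 higher and 2 lower of 15 (7 and 2 adjusted over the list alone, adjusted p = 0.519 with an estimated correlation), not passing after rescaling. Cholesterol synthesis and uptake passed downward, with 0 higher and 18 lower of 22 (1 and 19 adjusted over the list alone, adjusted p = 0.245 with an estimated correlation) and rescaled 2 and 10. It did not pass at a minimum of 5 TPM or without Saline replicate 1. In total 9022 genes differed, 1980 higher and 7042 lower. Rescaled there were 3567 and 3274, and with upper-quartile scaling 2559 and 5363.

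**Figure D2:**
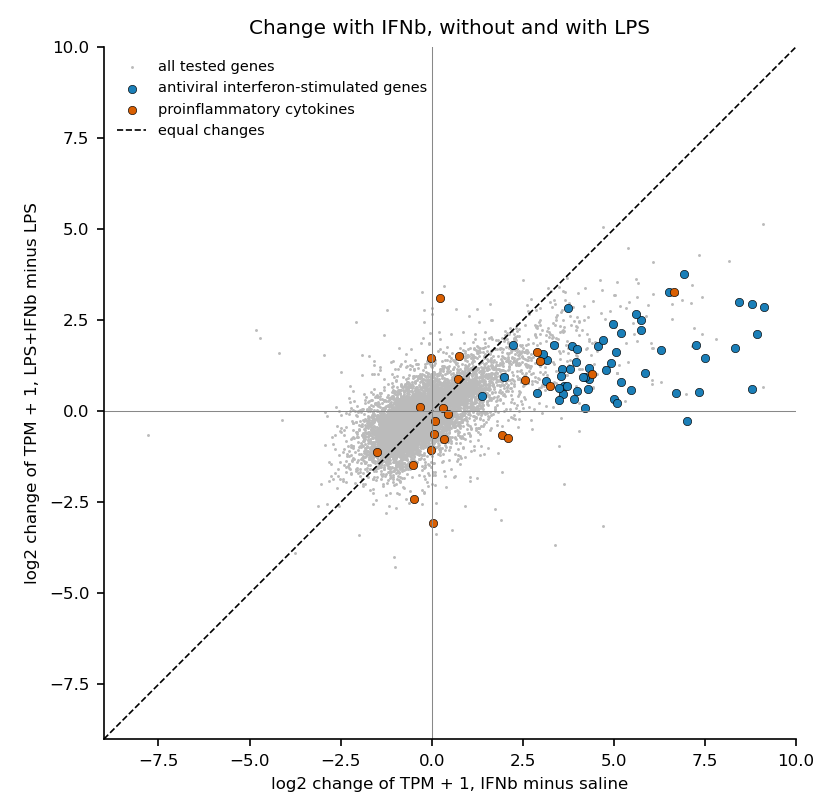
Log2 change of TPM + 1 with IFNb in the presence of LPS (LPS+IFNb minus LPS) against that without it (IFNb minus saline), 1 point per tested gene of 13009, with antiviral interferon-stimulated genes and proinflammatory cytokines in colour. The diagonal marks equal changes, and 56 of 57 antiviral genes have an interaction call below it.

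The interaction asks whether the log2 change with IFNb differed when LPS was also given, which is the same number as whether the change with LPS differed after IFNb. Interferon-induced genes made up the 8 most negative values. Of 57 antiviral interferon-stimulated genes 56 had a negative interaction (56 adjusted over the list alone) with a median of -3.22, and adjusted p = 0.0292 with an estimated correlation. Of 18 guanylate-binding proteins and immunity-related GTPases 15 did (15 adjusted over the list alone), with a median of -3.71 and adjusted p = 0.0292 with an estimated correlation. The most negative genes were Cxcl10 (-8.44 ± 0.17), Ifit1 (-8.17 ± 0.22), Mx1 (-6.82 ± 0.16), Cmpk2 (-6.81 ± 0.13), Rsad2 (-6.57 ± 0.14), Gbp5 (-6.52 ± 0.11), Ifit2 (-6.25 ± 0.39) and Oasl1 (-6.20 ± 0.45), each of which rose with LPS alone and with IFNb alone. Of the proinflammatory cytokines 10 of 23 had a negative interaction and 1, Ifnb1 (2.88 ± 0.57, adjusted p = 0.0321), a positive one (11 and 1 adjusted over the list alone; adjusted p = 0.0572 with an estimated correlation). Tnf had -2.57 ± 0.15, Il6 -1.71 ± 0.36 (adjusted p = 0.0377) and Tnfsf10 -3.36 ± 0.21, whereas Il1b had -0.98 ± 0.37 (adjusted p = 0.178, or 0.0353 without IFNb replicate 1), Il12b -1.91 ± 0.90 (adjusted p = 0.269) and Nos2 -0.25 ± 0.45 (adjusted p = 0.813). The sign for Nos2 was positive without LPS replicate 2 (0.26), and with a pseudocount of 0.1 its interaction passed (-2.57, adjusted p = 0.0307). Il10 had -1.18 ± 0.19 (adjusted p = 0.0153), or -2.98 with a pseudocount of 0.1. The call of Il6 was lost with no filter on low values (adjusted p = 0.0948) and without Saline replicate 1 (0.0743), LPS replicate 1 (0.116), LPS replicate 2 (0.108), IFNb replicate 1 (0.101), LPS+IFNb replicate 1 (0.0706) or LPS+IFNb replicate 2 (0.121), and with a pseudocount of 0.1 its value was -3.17. The call of Ifnb1, which was listed at 0 in saline, was lost with a pseudocount of 0.1 (1.84, adjusted p = 0.185), with no filter (0.0904) and without any 1 library of the saline (0.0715 and 0.0757), LPS (0.0967 and 0.103) or IFNb group (0.10 and 0.109). The call of Il10 was lost without LPS replicate 1 (0.0532), IFNb replicate 1 (0.0577), IFNb replicate 2 (0.0696), LPS+IFNb replicate 1 (0.0690) or LPS+IFNb replicate 2 (0.0600). Chemokines had 9 of 23 negative (adjusted p = 0.195 with an estimated correlation), among them Ccl4 (-4.59 ± 0.22) and Ccl2 (-5.21 ± 0.29), and MHC class I presentation 11 of 23 (adjusted p = 0.346 with an estimated correlation), with Tap1 at -2.51 ± 0.10.

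Further lists passed in the negative direction (adjusted p with an estimated correlation). Other pattern receptors had 0 positive and 9 negative of 23 (1 and 11 adjusted over the list alone, adjusted p = 0.134). Feedback regulators had 2 positive and 9 negative of 26 (3 and 10 adjusted over the list alone, adjusted p = 0.503), and inflammasome and cell death had 0 positive and 7 negative of 23 (0 and 7 adjusted over the list alone, adjusted p = 0.503). Interferon receptor, JAK-STAT and IRF genes had 1 positive and 6 negative of 21 (5 and 9 adjusted over the list alone, adjusted p = 0.503). Costimulation and adhesion had 0 positive and 5 negative of 16 (0 and 7 adjusted over the list alone, adjusted p = 0.341). The NF-kB pathway had 1 positive and 7 negative of 28 (1 and 11 adjusted over the list alone, adjusted p = 0.503), not passing with fry. TLR4 sensing and signalling had 1 positive and 4 negative of 22 (1 and 8 adjusted over the list alone, adjusted p = 0.656). The call was lost with fry, with the replicate block, at a minimum of 5 TPM, or without Saline replicate 1, Saline replicate 2, LPS replicate 1, IFNb replicate 2 or LPS+IFNb replicate 1. B cell markers passed in the positive direction, with 1 positive, Cd79b (1.22 ± 0.21), and 0 negative of 21 (1 and 0 adjusted over the list alone, adjusted p = 0.656 with an estimated correlation). This list did not pass with fry or without Saline replicate 1, LPS replicate 2, IFNb replicate 1 or LPS+IFNb replicate 2. The limma call of Cd79b itself was lost without LPS replicate 2 (adjusted p = 0.0548), IFNb replicate 1 (0.0806), IFNb replicate 2 (0.0581), LPS+IFNb replicate 1 (0.0643) or LPS+IFNb replicate 2 (0.0677).

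Positive interactions were led by Hamp (3.54 ± 0.17, adjusted p = 6.90e-05), at 0.50 ± 0.0266 TPM in saline, 17.5 ± 1.40 with LPS, 0.254 ± 0.0208 with IFNb and 179.7 ± 10.1 with LPS+IFNb. The phosphatase Dusp7 (3.25 ± 0.26), Cxcr4 (2.95 ± 0.23), Susd3 (2.91 ± 0.42), the DNA-damage inducible Gadd45a (2.74 ± 0.17), Klhl24 (2.72 ± 0.15), the stress cytokine Gdf15 (2.63 ± 0.31) and the growth factor Pdgfa (2.58 ± 0.37) followed. In total 1036 genes had an interaction, 457 positive and 579 negative. Of the 579, 504 were higher with IFNb alone, and of the 457, 389 lower, which shared IFNb and saline libraries favour. Of the 457, 48 were higher with LPS+IFNb than in each other group. Rescaled, 899 genes had an interaction, 269 positive and 630 negative. This split depended on libraries and settings. In protein-coding genes alone, a fit chosen after seeing the data, it was 623 and 567. It was 453 and 496 without Saline replicate 1, 243 and 612 without Saline replicate 2, 162 and 358 without LPS replicate 1, and 158 and 388 without LPS replicate 2. It was 129 and 340 without IFNb replicate 1, and 152 and 351 without IFNb replicate 2. Without LPS+IFNb replicate 1 it was 182 and 356, and without LPS+IFNb replicate 2 it was 160 and 383. At an adjusted p under 0.01 it was 95 and 306, at a minimum of 2-fold 284 and 436, with no filter on low values 294 and 460, and with the replicate block 263 and 465.

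The effect of IFNb without and with LPS, measured on separate libraries, correlated at r = 0.683 (Spearman 0.623) across 13009 genes, which are not independent replicates. Genes higher in both numbered 1098 against 183 for independent lists and genes lower in both 2540 against 1207, while 33 were higher with IFNb alone and lower with LPS+IFNb than with LPS, and 51 the reverse. All 84 had an interaction call, which opposite changes favour by construction. The effect of LPS without and with IFNb correlated at r = 0.697 (Spearman 0.652), with 867 genes higher in both against 146 and 3176 lower in both against 1637. Another 103 were higher with LPS alone and lower with LPS+IFNb than with IFNb, and 30 the reverse. All 133 likewise had an interaction call.

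**Figure D3:**
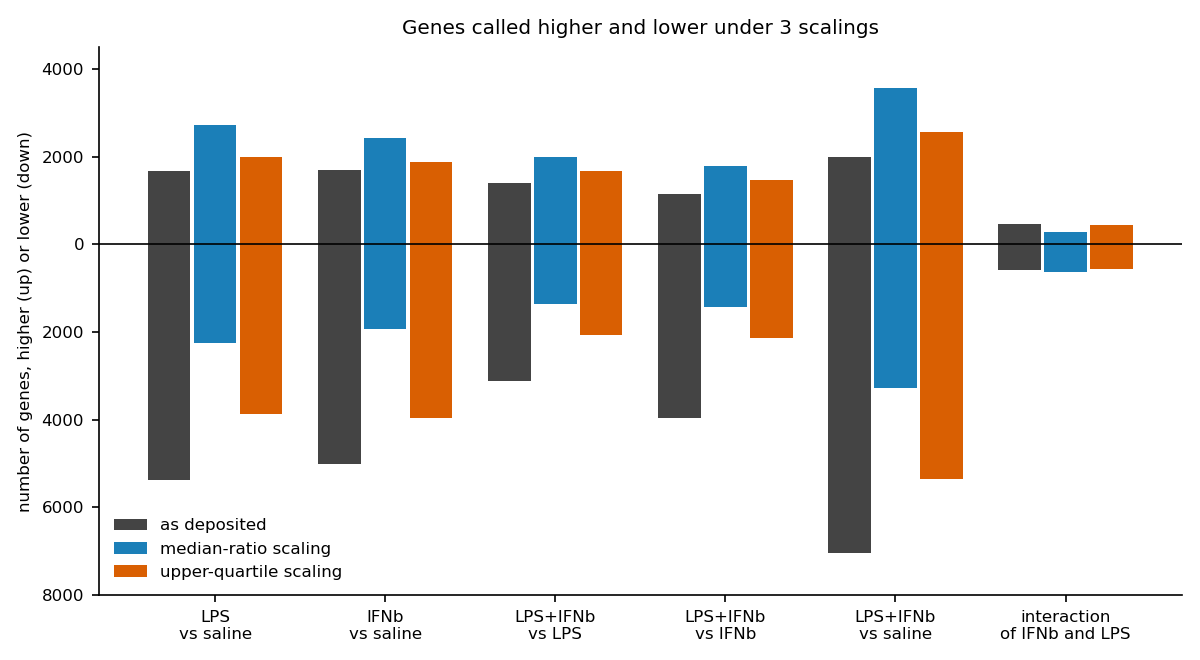
Genes called higher (up) and lower (down) in each comparison, as deposited and after median-ratio and upper-quartile scaling, from 13009 tested genes. As deposited, LPS against saline has 1664 higher and 5368 lower, and median-ratio scaling gives 2718 and 2254.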

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

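Of the tests in this part, those of the pseudocount and of the time since IFNb, and the repeats of the additivity test on rescaled values, were chosen only after the result was seen. Each value was flagged because the effect of IFNb differed with and without LPS by limma's interaction test (1036 genes) or camera's for a list.

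The gene values were -8.44 for Cxcl10, -8.17 for Ifit1, -6.82 for Mx1, -6.81 for Cmpk2, -6.57 for Rsad2, -6.52 for Gbp5, -6.25 for Ifit2, -6.20 for Oasl1, -6.05 for Isg15, -5.51 for Socs1 and -3.23 for Irf7, all of them raised by IFNb alone. Among mediators Tnf had -2.57, Il6 -1.71, Il10 -1.18 and Ifnb1 2.88. In TPM, Il6 and Il10 were more than additive (LPS+IFNb above LPS and IFNb summed), unlike Tnf. Only the antiviral list had an additivity test. Positive values were Hamp 3.54, Dusp7 3.25, Cxcr4 2.95, Susd3 2.91, Gadd45a 2.74, Klhl24 2.72, Gdf15 2.63 and Pdgfa 2.58. The lists that passed had median interactions of -3.71 for guanylate-binding proteins and immunity-related GTPases, -3.22 for antiviral interferon-stimulated genes, -1.07 for proinflammatory cytokines, -1.0 for chemokines, -0.83 for costimulation and adhesion, -0.64 for MHC class I presentation, -0.38 for feedback regulators, -0.35 for interferon receptor, JAK-STAT and IRF genes, -0.32 for the NF-kB pathway, -0.28 for other pattern receptors, -0.14 for inflammasome and cell death, -0.12 for TLR4 sensing and signalling and 0.47 for B cell markers. With an estimated correlation only the first 2 passed.

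For the negative interaction of 56 of 57 antiviral interferon-stimulated genes, a pseudocount of 0.1 gave 56 negative calls as well, which decides nothing on the pseudocount of 1, since a smaller one pushes genes that are lowest in saline further down. Responses that add up in TPM, which look smaller than additive on the log scale, stay open: TPM after both treatments divided by the sum of the single effects had a median of 0.664 (quartiles 0.559 and 0.739). That lies under the bound of 0.8 set against it, but the bound took the deposited scale as given, and the median was 0.749 (0.633 and 0.847) with upper-quartile and 0.822 (0.695 and 0.929) with median-ratio scaling. The ratio was below 1 in 54, 52 and 47 of 57 genes on the 3 scales, which goes against exact additivity, but the last median lies above the bound. Time since IFNb cannot be told apart from the effect of LPS, because no group had IFNb and then saline: 13 of the 57 genes were lower 8 h after IFNb with LPS than 4 h after IFNb alone, and 1 of the 57 after median-ratio scaling. A response to LPS that prior IFNb alters, the biological explanation given by the design, may hold too and was not tested apart from these.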

How the results depend on the processing

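Named genes, picked largely for strong calls, mostly kept direction and side of the threshold. Of 206 gene results, 201 held with median-ratio scaling, 204 with upper-quartile scaling, 203 with a pseudocount of 0.1 and 202 with no filter. Those lost are given beside their values. Over all genes, median-ratio scaling kept from 2563 of 5107 calls (LPS+IFNb against IFNb) to 819 of 1036 (interaction). Depth is unknown, so the error of low genes has no floor. With a library left out, the lone library of its group is assumed to vary like the other groups. DESeq2, limma-voom and length-scaled counts were not run, since they need counts or effective lengths; scaling by library size alone and log2(TPM + 1) equal the values reported.

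An adjusted p under 0.01 gave 4639 genes in LPS against saline, 4263 in IFNb against saline, 2328 in LPS+IFNb against LPS, 2413 in LPS+IFNb against IFNb and 401 in the interaction. A minimum of 2-fold gave 3028, 2577, 1322 and 1511 in the first 4 and 5270 in LPS+IFNb against saline. Median-ratio scaling gave 4367 in IFNb against saline and 3211 in LPS+IFNb against IFNb; it takes away falls shared by most genes. Leaving out each library gave 5300 to 6742, 4717 to 6496, 2723 to 4975, 2491 to 5542, 7854 to 8839 and 469 to 949 genes in the 6 comparisons in the order of the report, with fewer samples. Protein-coding genes alone, a fit chosen after seeing the data, gave 7409, 7130, 4750, 5459, 8993 and 1190. The correlation of the IFNb effects without and with LPS was 0.589 with a pseudocount of 0.1, 0.665 with no filter, 0.721 with a minimum of 5 TPM, 0.733 in protein-coding genes and 0.644 to 0.678 with a library left out. That of the LPS effects without and with IFNb was 0.630, 0.685, 0.726, 0.742 and 0.661 to 0.687, and that of the LPS and IFNb effects 0.527 to 0.580 with a library left out. The cause was not tested.

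Deviations of libraries with the same replicate number correlated at only -0.156 to 0.141, but weak pairing of the samples could give this too. With the replicate number as a block the counts were 6766, 6493, 4140, 4606, 8909 and 728 genes and 112 lists passed; among named results it ended the calls of Il6 in LPS+IFNb against LPS (adjusted p = 0.0580) and in the interaction (0.0625), of complement in LPS+IFNb against LPS and of TLR4 sensing and signalling in the interaction.

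Of 114 passing list results 11 passed with an estimated correlation. With the other settings 99 passed after median-ratio scaling, 105 with upper-quartile scaling, 100 with a minimum of 5 TPM, 102 to 116 with a library left out, 136 with fry and 132 with fry and the block. Lists given as not passing that passed with fry were cell cycle (adjusted p = 0.00209) and B cell markers (0.00609), both downward, in LPS against saline. In LPS+IFNb against LPS they were TLR4 sensing and signalling (0.0141), downward, and dendritic cell (0.0293) and eosinophil markers (0.0353) and proinflammatory cytokines (0.0156), upward. In LPS+IFNb against IFNb they were guanylate-binding proteins and immunity-related GTPases (0.0273), downward. Ifnar1 in IFNb against saline had 0.24 after median-ratio scaling, Irf7 in LPS+IFNb against IFNb 0.25, and 0.12 with upper-quartile scaling, and the interaction of Nos2 0.00095 after median-ratio scaling and -0.75 to 0.26 with a library left out. Of the lists named, 23 turned direction under at least 1 setting, 5 of them called, with adjusted p in brackets. After median-ratio scaling the direction turned for cell cycle (0.928) in IFNb against saline, large peritoneal macrophage markers (0.957), chemokines (0.884) and cholesterol efflux and LXR targets (0.912) in LPS+IFNb against LPS, guanylate-binding proteins and immunity-related GTPases (0.615) and oxidative phosphorylation (0.801) in LPS+IFNb against IFNb and mitochondrially encoded (0.821), oxidative phosphorylation (0.192) and ribosomal proteins (0.366) in LPS+IFNb against saline. With upper-quartile scaling it turned for cholesterol efflux and LXR targets (0.974) in LPS+IFNb against LPS and guanylate-binding proteins and immunity-related GTPases (0.831) in LPS+IFNb against IFNb. With a minimum of 5 TPM it turned for cell cycle (0.998) in LPS against saline, neutrophil markers (0.861) and cholesterol efflux and LXR targets (0.861) in LPS+IFNb against LPS and guanylate-binding proteins and immunity-related GTPases (0.990) in LPS+IFNb against IFNb. With fry it turned for MHC class II presentation (0.565 and 0.634 with the block) and monocyte markers (0.920) in LPS against saline. With fry it also turned for cell cycle (0.625 and 0.660 with the block) and T and NK cell markers (0.984 and 0.908 with the block) in IFNb against saline. With fry it also turned for MHC class II presentation (0.910 and 0.960 with the block), antimicrobial and arachidonate effectors (0.535 and 0.584 with the block), B cell markers (0.655 and 0.714 with the block), large peritoneal macrophage markers (0.455 and 0.462 with the block), mast cell markers (0.814 and 0.825 with the block), chemokines (0.276 and 0.170 with the block) and unfolded protein response (0.183 and 0.295 with the block) in LPS+IFNb against LPS. With fry it also turned for MHC class I presentation (0.502 and 0.568 with the block), antiviral interferon-stimulated genes (0.0740 and 0.0946 with the block), monocyte markers (0.158 and 0.280 with the block) and large peritoneal macrophage markers (0.973 with the block only) in LPS+IFNb against IFNb. With each library left out in turn, it turned at least once, with these ranges of adjusted p, for MHC class II presentation (0.385 to 0.880) in LPS against saline and MHC class II presentation (0.123 to 0.963), antimicrobial and arachidonate effectors (0.458 to 0.901), large peritoneal macrophage markers (0.389 to 0.816), mast cell markers (0.214 to 0.922), neutrophil markers (0.301 to 0.881), chemokines (0.621 to 0.922), cholesterol efflux and LXR targets (0.744 to 0.922) and unfolded protein response (0.579 to 0.906) in LPS+IFNb against LPS. The cause of these was not tested.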

Other observations

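Of the tests in this part, those of a few raised genes taking more of the TPM, the version of the low-level test based on saline levels, the per-million scale for cytokines and the set of LPS-induced genes that IFNb alone did not raise were chosen only after the result was seen. Genes named in the next 2 paragraphs were chosen after their values were seen.

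Genes induced by LPS split by whether IFNb alone raised them. Of 427 genes raised at least 4-fold by LPS alone, 243 were also raised by IFNb alone, and of these 153 were higher and 17 lower with LPS+IFNb than with LPS, with a median log2 change of 0.83. Of the other 184, 9 were higher and 80 lower, with a median of -0.62. Rescaled by the median ratio the counts were 171 and 8 against 14 and 56. Both sets were picked on the LPS libraries, which pushes their change from LPS to LPS+IFNb downwards. Among the 48 genes with a positive interaction that were higher with LPS+IFNb than in each other group, the endothelial protein C receptor gene Procr was at 19.1 ± 0.121 TPM in saline, 29.2 ± 1.61 with LPS, 10.1 ± 1.34 with IFNb and 70.9 ± 1.32 with LPS+IFNb.

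A pair of cell cycle genes moved apart from most of their list, of which 2 of 24 were higher and 6 lower with LPS than with saline, and 4 and 7 with IFNb (camera adjusted p = 0.582 and 0.747). Mki67, the proliferation marker Ki-67, was at 1.46 ± 0.104 TPM in saline, 19.3 ± 0.125 with LPS, 0.712 ± 0.00541 with IFNb and 16.7 ± 2.03 with LPS+IFNb, all of it from a 10061-nt transcript. Tpx2, a spindle assembly factor, was at 3.77 ± 0.190, 3.88 ± 0.429, 42.3 ± 0.0859 and 49.6 ± 1.14 TPM in the same order. Part of its value came from a retained-intron transcript of Tpx2, at 0 in both saline libraries and 16.8 and 13.8 TPM with IFNb, and a protein-coding transcript went from 2.09 and 1.53 to 19.9 and 19.6 TPM. The unprocessed pseudogene Gm29013, 237 bases on chromosome 1 (105244425 to 105244661), held 10092 to 31637 TPM per library and was the top gene in Saline replicate 1, IFNb replicate 1 and LPS+IFNb replicate 2.

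For the cytokine genes that moved both ways when LPS followed IFNb, the per-million scale of TPM is argued against as the whole cause, since after median-ratio scaling 9 cytokine genes were higher and 4 lower, the latter being Il1a (-0.85), Il1b (-1.21), Il12b (-2.15) and Il23a (-2.84). A lower share of LPS-responding macrophages after IFNb stays open as a cause of the falls: of the genes raised at least 4-fold by LPS 37.9% were higher with LPS+IFNb, above the bound of 10% set against it, but that bound was wrong, because 153 of those 162 genes are raised by IFNb itself. Among the genes that IFNb alone did not raise 4.89% were higher, while their log2 changes spread from a lower quartile of -1.04 to an upper quartile of -0.10, so a smaller share and a gene-specific effect of prior IFNb cannot be told apart. That effect, which the design names, may account for rises and falls and was not tested apart from the extra 4 h since IFNb.

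As deposited, lower genes outnumbered higher ones against saline in each of 3 comparisons. After median-ratio scaling higher ones did, 2718 against 2254 in LPS, 2429 against 1938 in IFNb and 3567 against 3274 in LPS+IFNb. A few raised genes taking more of the TPM stays open. The median log2 change of the genes not called higher lay below that of their summed TPM by a difference of -0.108 in LPS (-0.198 to -0.0510 with each library left out), -0.0396 in IFNb (-0.119 to -0.00728) and -0.167 in LPS+IFNb (-0.257 to -0.118). These genes were chosen by their own change, which favours a negative difference, so this cannot be told apart from a fall of many genes. Fuller detection of low-level transcripts in saline likewise stays open: among called genes with a mean of at least 50 TPM, higher ones made up 46.6% in LPS, 43.0% in IFNb and 40.9% in LPS+IFNb, but 22.3%, 22.3% and 19.1% among called genes with at least 50 TPM in saline, and either way of choosing genes favours an outcome. A biological fall of many transcripts with treatment, which could be part of the pattern, was not tested without a spike-in or a total RNA amount.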
